A study of Mus musculus with 35 samples.

How the data were processed

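Pancreatic lymph node RNA of female NOD mice was hybridised in the Cy3 channel and pooled NOD.B10 RNA in the Cy5 channel of Agilent whole mouse genome arrays. Each of the 35 arrays was one sample, assigned to its age by its label. Per the labels' protocols, RNA was isolated with RNeasy columns and labelled with a linear amplification kit for low RNA input. No array had its dyes exchanged, so a dye bias of a gene stays in its ratio to the control and drops out of a difference between ages only if it is constant. The submitters' processing notes name Feature Extraction 8.5, whereas the file headers give version 8.1.1.1 on 11 arrays and 8.5.1.1 on 24. The arrays were read on 6 scan days with 5 scanners.

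The processed intensities of both channels were background-subtracted with spatial detrending and dye-normalised within each array (linear and lowess), per the file headers, and low signals had been replaced by a surrogate. The mean spot intensity and the median local background intensity were raw pixel values, per the file headers. The deposited value is a log10 ratio of NOD over NOD.B10. It equalled the negative of the scanner's log10 ratio within 5e-10, which settles its direction and scale, and was 0 for spots with surrogate signals (2.83% to 29.1% of spots on an array). The median deposited log10 value of an array lay between -0.0121 and 0.00072, with no further centring found. An array held 40339 to 41534 spots other than controls. On replicate 1 at 10 days 1195 spots had a deposited value but no scanner entry and were left out. Flags for signal over background, saturation and outliers came from Feature Extraction.

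The value analysed was the log2 ratio of the processed signals, NOD over NOD.B10, whose median on an array lay between -0.153 and 0.0421. Control spots and spots with an outlier flag were left out, saturated spots were kept, and spots of one probe were averaged. Probes had to be well above background in either channel on at least 4 arrays, which kept 40837 of 41174 probes and dropped 337. Each gene was represented by its brightest probe, giving 28371 genes, of which 18197 had a symbol and 22835 a value on every array. Gene names came from the array files and were updated through a gene table (assembly GRCm38.p6), which matched 22161 probes by accession, 5106 by symbol and 4391 by synonym, while 9516 matched none and kept the name in the file. Chromosomes and gene order came from the same table, and no coordinates are given because the build of the array design is not given in the sources used here.

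Group means of the 6 ages were fitted in one model over all arrays with limma 3.58.1 (lmFit and eBayes), and p-values were adjusted by Benjamini-Hochberg at 0.05. A strain ratio at an age was tested against 0 and had to reach an absolute log2 ratio of 1. Ages were compared by moderated F tests over the 6 ages and over 4 to 20 weeks, and by 7 differences between pairs of ages. The 35 gene lists, with 838 distinct measured genes of which 31 were in more than 1 list, were tested with camera at a preset correlation of 0.01, in 280 pairs of list and comparison, with adjustment within a comparison. The lists, tests, naming rule and most alternatives were fixed before the data were examined. The channels were also fitted alone, as quantile normalised log2 signals. A probe well above background on no array of a group, or saturated on every array of it, has only a bound there. For a strain ratio the brighter channel was then set against the dimmer one at the higher of its own signal and the lowest signal among probes well above background ("at least", open to dye bias), and for a difference between ages no fold is printed. Where only part of the arrays of the compared ages measured a named probe or part of them were saturated, their number is given. Fisher's exact test compared the shares of genes on chromosome 17, and permutation tests used 100000 draws.

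Genes were named by a rule. For the strain ratio it took up to 15 of the highest and 15 of the lowest mean ratios among genes past the threshold at every age with the same sign on all arrays. For 4 weeks and 20 weeks against 10 days and 20 against 4 weeks it took the 10 highest and 10 lowest differences among genes past the threshold whose groups did not overlap, and for other steps the 5 highest and 5 lowest. It added the 10 smallest p-values of each F test, up to 4 leading members of each passing list, and Deaf1, Aire, Ins1, Ins2, Foxp3, Ctla4, Il2, Ifng, H2-K1, H2-D1, H2-Aa, H2-Ab1 and H2-Eb1. Genes without a symbol were counted but not named, and genes with the smallest changes were left out for length, as were the genes that only an F test named.

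Alternatives were normexp background correction (offset 50) with loess, the deposited values, other filters on dim probes, centring of each array on its median, all probes, batch and replicate blocks, fits to the compared groups, each array left out in turn, the NOD channel alone, other size limits and other list tests. Up to 100 splits of the arrays per result, the real one included, gave counts by chance. The procedure was tested on simulated data for 20 against 16 weeks over 28371 genes. It called 47 of 100 genes changed by 1 on the log2 scale, 96 of 100 changed by 2 and 13 unchanged genes, which were 8.33% of all calls. In the same simulated data it called 0 genes between 12 and 8 weeks, passed the 1 changed list and passed 0 of 34 unchanged lists. The simulated genes varied independently of each other, so the simulation does not show how often lists of correlated genes pass by chance. Other software was R 4.3.3 with version 1.17.8 of data.table, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.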

Results

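Gene expression was measured in pancreatic lymph nodes, which drain the pancreas, of female NOD mice, an inbred strain that develops autoimmune diabetes. Each of 35 two-colour whole mouse genome arrays carried NOD RNA in the Cy3 channel and pooled RNA of NOD.B10 mice, a related strain with another major histocompatibility complex (MHC) haplotype that served as the control, in the Cy5 channel. The NOD mice were 10 days (n = 7), 4 weeks (n = 6), 8 weeks (n = 4), 12 weeks (n = 7), 16 weeks (n = 6) and 20 weeks (n = 5) old. Values below are log2 ratios of NOD over NOD.B10, so a positive value is higher in NOD. The share of probes well above background on an array ran from 42.1% to 93.5% in the NOD channel and from 36.3% to 90.2% in the control channel, and the number of arrays limits the precision. The series description names control RNA from 2 pools of 10 mice each, 10 days and 20 weeks old. The labels do not say which pool was used on which array, or whether these were the only ones. The control counts as 1 sample whose own spread is left out, and since nothing states that the arrays of a group came from separate animals, the p-values measure the spread between arrays, which may be technical. Dyes were not swapped. The labels give the dye of each strain and the ages differ, so the direction was kept although the ratios of 1 pair of arrays, replicate 2 at 4 weeks and replicate 2 at 16 weeks, correlated at r = -0.31 across probes, which are not independent.

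The first comparison asked which genes differed between the strains. D17H6S56E-5, an MHC region transcript, and H2-T3, a non-classical class I gene, both on chromosome 17, passed the threshold at every age. The D17H6S56E-5 ratio was -2.96 ± 0.32 (SD, n = 7) at 10 days and -4.24 ± 0.27 (n = 7; NOD signal well above background on 5 of the 7 arrays) at 12 weeks, with a mean over the 6 ages of -3.76 ± 0.08 (SE; 13.5-fold lower probe signal in NOD). The H2-T3 ratio was 1.34 ± 0.44 (SD, n = 7) at 10 days. Its control signal was not well above background on any array at 4, 8 and 12 weeks, where the NOD signal was at least 2.50-fold, 3.09-fold and 3.30-fold higher. Each kept its sign on every array with a value, as did 2 further probes without a gene symbol. With a size limit of 1 on the log2 scale and an adjusted p under 0.05 (limma), these 4 genes were the ones that passed at all 6 ages. After normexp background correction and loess 1 gene passed, with the scanner as a block 2, and among probes well above background in both channels on all arrays 0. These ratios come from single probes, and probes of one MHC gene can disagree. At 12 weeks the 2 H2-Aa probes stood at 0.65 and -2.58, while the H2-Ab1 probes lay between -0.10 and 0.75. The ratio of a single probe need not be that of the RNA, which was not tested.

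Without the size limit, 19 genes passed at every age, of which 12 lay on chromosome 17, 2 on other chromosomes and 5 were not placed. The chromosome 17 genes included H2-T23 (mean ratio -1.32), H2-DMb1 (-1.25), which encodes a chaperone of class II peptide loading, Gfer (-1.26), Zfp871 (-1.10) and Dnah8 (1.36), and the other 2 were Msra (0.80) and Suclg2. These last 5 fell outside the rule for named genes and were chosen after their values were seen. H2-M2, a further class I gene of the MHC, had a mean ratio over the ages of -1.12 ± 0.04 (SE). Chromosome 17 held 2 of 918 tested genes past the size limit at every age against 0 of 18404 on the other chromosomes (Fisher's exact test, two-sided, p = 0.00225, adjusted p = 0.00526). It held 1 such gene (Fisher's exact test, p = 0.0475) after normexp background correction, with the Feature Extraction version or the scanner as a block and with acinar and islet scores as covariates, and 0 (p = 1) among probes well above background in both channels on all arrays. At 4 weeks 15.7% of the chromosome 17 genes passed against 10.1% elsewhere (adjusted p = 2.83e-06), and at 8 weeks 2.07% against 0.744% (adjusted p = 0.000548). At 10 days, 12, 16 and 20 weeks the adjusted p was 0.591, 0.0573, 1 and 0.220.

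**Figure D1:**
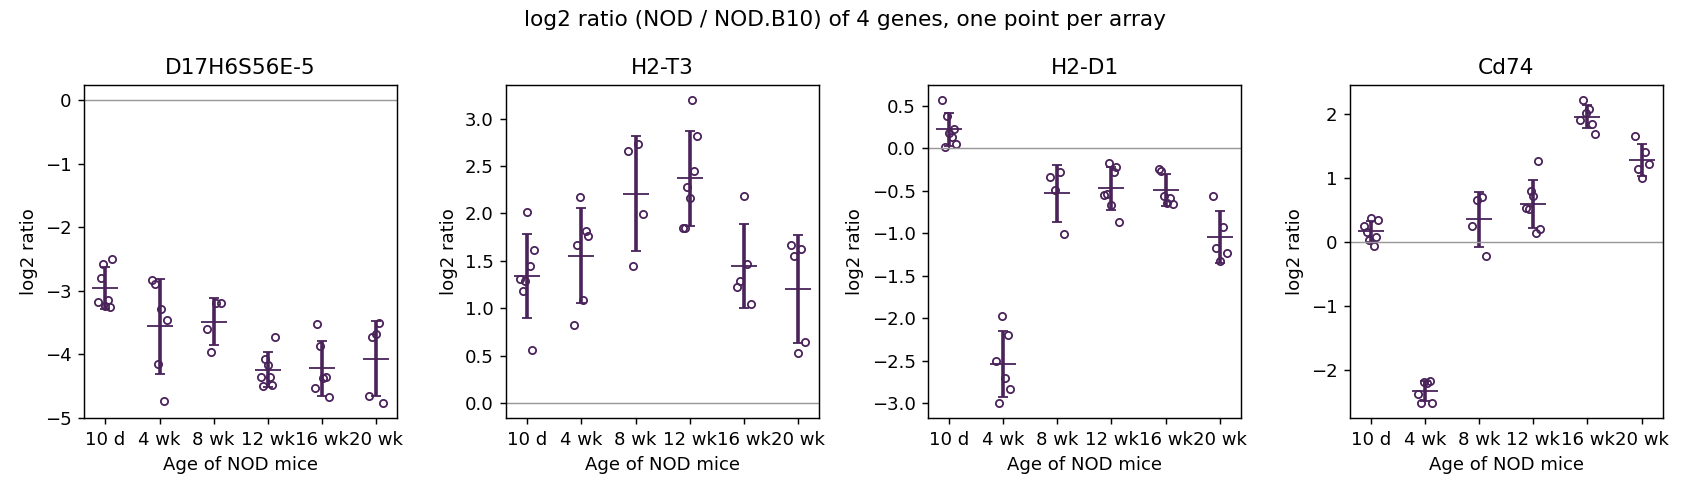
The plots show the log2 ratio of NOD over NOD.B10 (y axis) against age (x axis) for D17H6S56E-5, H2-T3, H2-D1 and Cd74, with 1 point per array and bars for the mean ± SD. D17H6S56E-5 lay below 0 and H2-T3 above 0 on every array with a value, whereas H2-D1 and Cd74 were lowest at 4 weeks, with means of -2.54 and -2.32.

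Pancreatic acinar genes, which encode digestive enzymes, had ratios of -2.32 ± 1.88 (mean over 29 genes, SD over arrays, n = 7) at 10 days, -0.67 ± 3.84 (n = 6) at 4 weeks, and -1.43 ± 3.17 (n = 4) at 8 weeks. They stood at -4.85 ± 2.46 (n = 7) at 12 weeks, -3.66 ± 2.71 (n = 6) at 16 weeks and 0.29 ± 1.19 (n = 5) at 20 weeks. Single arrays set some of these means. Without replicate 2 the mean at 8 weeks was 0.15, at 4 weeks it ran from -1.25 (without replicate 2) to 0.58 (without replicate 5) and was 0.00 without replicate 3, -1.22 without replicate 4 and -1.13 without replicate 6, and at 20 weeks it was 0.74 without replicate 1, 0.030 without replicate 3 and 0.0086 without replicate 5. A ratio with a saturated signal is only a bound, and 23 of the 29 acinar genes had a saturated control signal on some array, 18 of them on every array at 16 weeks. The 6 genes without saturated signals at 16 and 20 weeks stood at -1.67, 0.27, -1.86, -5.12, -4.12 and -0.18 from 10 days to 20 weeks. For the mean ratio over the 6 ages 13 of 35 lists passed the set test (camera with a preset correlation), 4 higher and 9 lower, with adjusted p from 7.91e-08 to 0.0499. None of the 13 held with an estimated correlation, where the adjusted p was 0.603 for 12 of them and 0.739 for the type I interferon list. Over the 6 ages 29 of 29 acinar genes were lower in NOD (median -2.08), among them Cela2a (-2.28 ± 0.41, SE; control signal saturated on 4 of 6 arrays at 16 weeks), and 17 of 23 islet genes (median -0.60), among them Chgb (-1.84 ± 0.24) and Gcg, which encodes glucagon and whose control signal at 4 weeks was not well above background on any array. Reg2, a regenerating-family gene of the exocrine pancreas, was lower too, with a control signal saturated on every array at 8 and 16 weeks. Erythroid genes were lower for 18 of 19 members (median -0.75), with Eraf, the alpha-haemoglobin chaperone, at -1.41 ± 0.19, Ermap at -1.12 ± 0.14 and Gata1 at -0.86 ± 0.10. Liver-secreted protein genes were lower for 13 of 17 (Afp -1.43 ± 0.14, Alb -1.52 ± 0.20) and adipocyte genes for 15 of 21 (Pck1 -1.76 ± 0.28, Car3 -1.41 ± 0.21). The liver list stood at -3.33 ± 0.95 (SD, n = 7) at 10 days and between -0.80 and 0.34 at the later ages. Lower ratios were also found for 34 of 46 cell cycle genes (Ccnf -1.05 ± 0.11, Cdc20 -0.78 ± 0.08) and 19 of 33 MHC genes, while 6 further MHC genes were higher. Of 24 epithelium and duct genes 15 were lower and 1 higher, and of 42 oxidative phosphorylation genes 25 were lower and 2 higher.

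Among 26 T cell genes 15 were higher in NOD and 3 lower for the mean over the 6 ages, with the signalling adaptor Lat at 0.49 ± 0.04 (SE) and the costimulatory receptor Cd28 at 0.56 ± 0.07. The T cell list did not keep 1 direction. It stood at 0.50 ± 0.08 (SD, n = 7) at 10 days, -0.11 ± 0.20 (n = 6) at 4 weeks and -0.13 ± 0.33 (n = 5) at 20 weeks. At 8, 12 and 16 weeks it stood at 0.14, 0.20 and 0.28. Immediate early genes were higher for 12 of 24 and lower for 1 (Klf2 0.69 ± 0.11, Egr3 0.60 ± 0.10). Interferon gamma response genes were higher for 8 of 22 and lower for 2 (Gbp4 0.68 ± 0.06). Type I interferon genes were higher for 10 of 31 and lower for 7 (adjusted p = 0.0499). The signals of Afp, Alb, Chgb, Reg2, Ermap, Gata1, Ccnf and Egr3 were well above background on only part of the arrays of some ages, the fewest being 1 of 6 at 16 weeks, for Ccnf in NOD and for Egr3 in the control. With acinar and islet scores as covariates 4 of the 13 lists turned direction, acinar (0.10), islet (0.063), epithelium (0.027) and type I interferon genes (-0.10), interferon gamma and oxidative phosphorylation genes lost the call, and 6 of the 23 genes followed lost it as well. Over the 13 lists 54 members were higher and 198 lower over all genes tested, and 56 and 203 when adjusted over the list alone. With probes well above background in both channels on all arrays, another Klf2 probe was used and its ratio was -0.72.

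**Figure D2:**
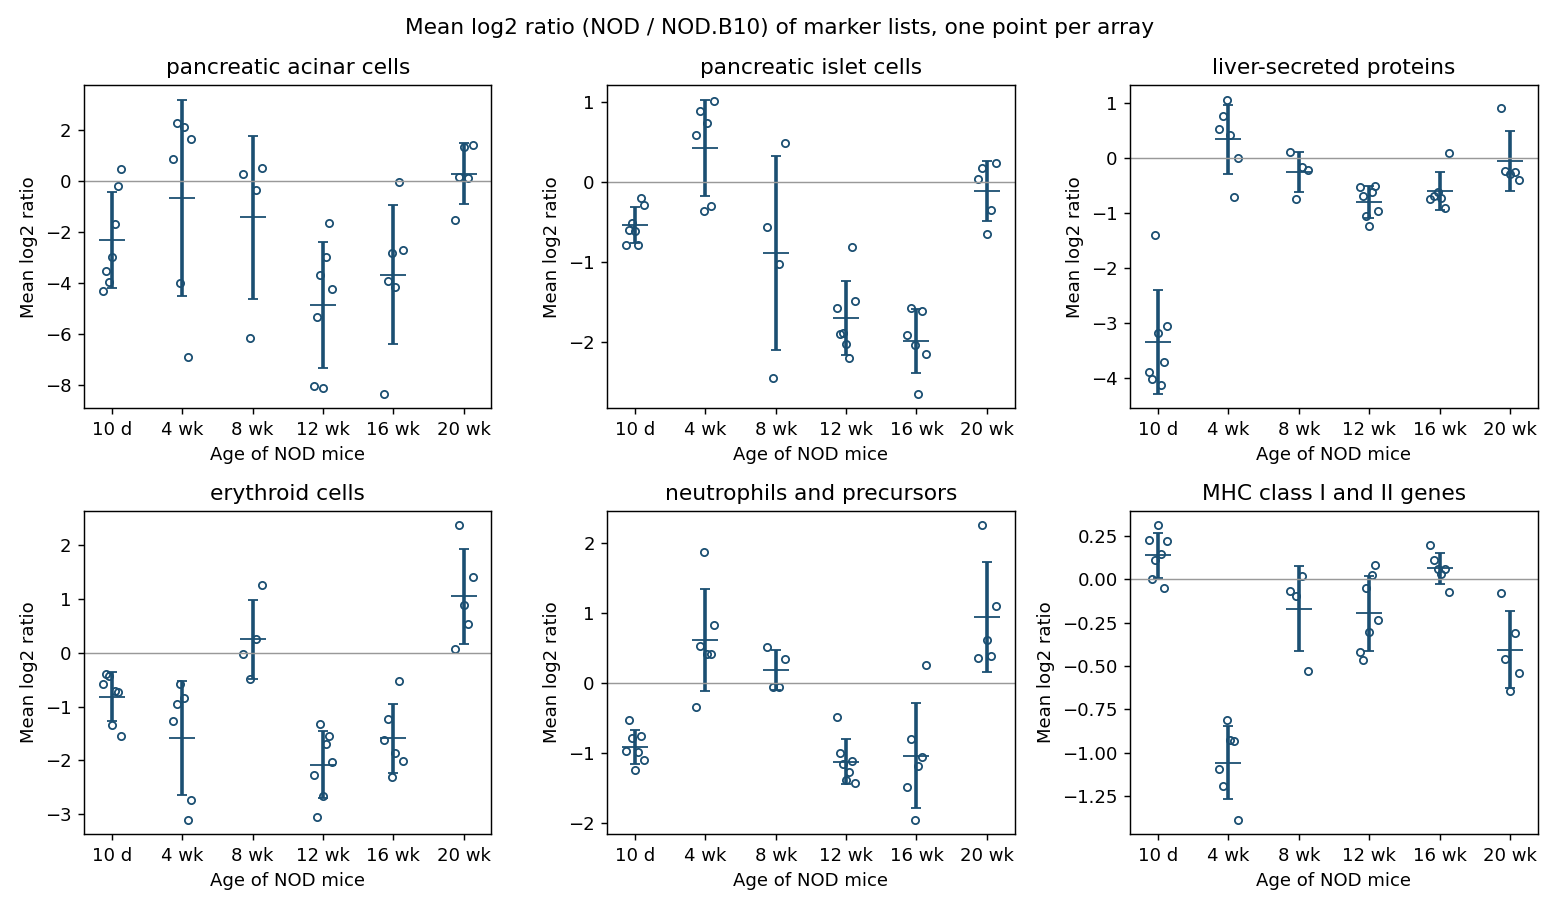
The plots show the mean log2 ratio of 6 marker lists (y axis) against age (x axis), with 1 point per array and bars for the mean ± SD over the arrays of an age. Acinar genes were lowest at 12 and 16 weeks, liver-secreted protein genes at 10 days and MHC genes at 4 weeks.

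Counts of genes past the threshold against the control, with the size limit, were 380 at 10 days (29 higher and 351 lower in NOD), 2786 at 4 weeks (985 and 1801) and 272 at 8 weeks (44 and 228). They were 1423 at 12 weeks (193 and 1230), 2065 at 16 weeks (654 and 1411) and 1237 at 20 weeks (296 and 941). Erythroid genes were at 0.25 ± 0.74 (SD, n = 4) at 8 weeks, -2.08 ± 0.62 (n = 7) at 12 weeks and 1.06 ± 0.88 (n = 5) at 20 weeks, and the mean at 8 weeks was -0.081 without replicate 4 and 0.50 without replicate 2. Genes of neutrophils and their precursors were at -0.91 ± 0.24 (n = 7) at 10 days, 0.62 ± 0.72 (n = 6) at 4 weeks and 0.94 ± 0.79 (n = 5) at 20 weeks, or 0.37 at 4 weeks without replicate 3 and 0.62 at 20 weeks without replicate 2. Without replicates 5 and 6 at 12 weeks, which correlated less with the other 5 arrays of that age (r from 0.22 to 0.38, across probes) than those did among themselves (0.47 to 0.73), 2279 genes passed at 12 weeks (572 higher and 1707 lower). At 10 days 100 were higher and 363 lower with the Feature Extraction version as a block, and 52 were higher with the scanner as a block. After normexp background correction and loess the counts in the same order were 164, 536, 40, 451, 524 and 157. At 8 weeks 170 genes passed in the deposited values (55 higher and 115 lower) and 4 in a fit to that age alone. At 20 weeks 468 were higher and 630 lower with each array centred on its median, and at 4 weeks 2820 probes were lower when all probes were counted.

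The next comparison asked whether the ratio changed with age. Of 28371 genes, 15398 differed among the 6 ages and 14419 among 4 to 20 weeks. Liver-secreted protein genes stood at a mean log2 signal of 13.37 ± 0.15 (SD, n = 7) in the control channel at 10 days and between 8.51 and 9.12 at the later ages. In the NOD channel their signal was at 9.67 ± 1.04 at 10 days and between 8.18 and 8.81 later. Acinar genes stood at 14.93 ± 0.19 (n = 7) in the control channel at 10 days, 18.45 ± 0.08 (n = 4) at 8 weeks and 18.39 ± 0.11 (n = 5) at 20 weeks, with 15 and 13 of the 29 genes saturated there on every array. Islet genes stood in the control channel at 8.48 ± 0.16 (n = 7) at 10 days, 7.43 ± 0.10 (n = 6) at 4 weeks and 9.81 ± 0.08 (n = 4) at 8 weeks. They stood there at 9.41 ± 0.22 (n = 6) at 16 weeks and 8.40 ± 0.12 (n = 5) at 20 weeks. Whether more than the 2 named control pools were used cannot be told from these values. Read by channel, 19563 genes differed with age in the control channel and 17636 in the NOD channel. The control channel thus differed between ages as well, so that the change of a ratio below is not a change within NOD alone, and its share in the control channel is given for each pair of ages. A share below 0 or above 1 means that both channels of a gene moved in the same direction. The median share is therefore no clean division of a change between the RNA of the strains. The arrays at 10 days, 4 weeks and 8 weeks were scanned on days that held no other age, so that for them scan day and age cannot be told apart. At 12, 16 and 20 weeks 17 arrays shared 1 day.

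**Figure D3:**
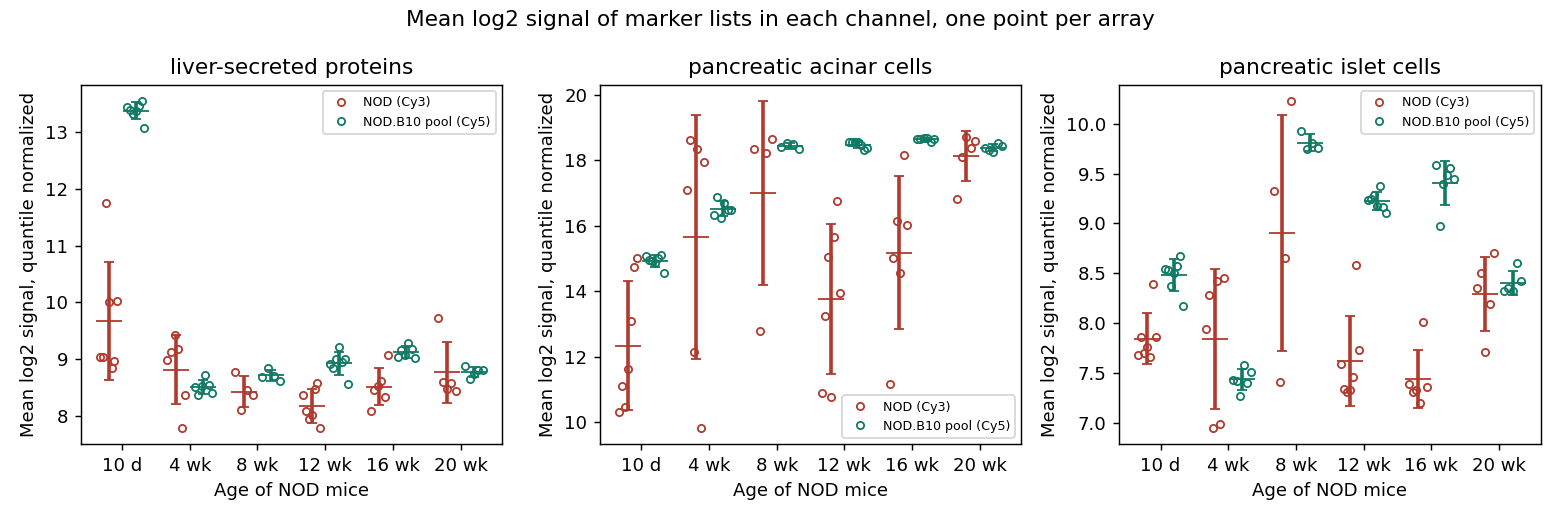
The plots show the mean log2 signal (y axis, quantile normalized) of liver, acinar and islet marker lists against the age of the NOD mice (x axis), for the NOD channel and the NOD.B10 control channel, with 1 point per array and bars for the mean ± SD. The control channel spread little within an age, with SDs of 0.05 to 0.23, where saturation limits the acinar signal from 8 weeks on, and the acinar signal of the NOD channel spread with SDs of 0.76 to 3.74.

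From 10 days to 4 weeks the ratio of liver-secreted proteins rose and that of MHC genes fell. Besides the liver list 10 lists passed, none of which held with an estimated correlation (adjusted p from 0.190 to 0.763). Afp, which encodes alpha-fetoprotein, went from -6.44 ± 1.57 (SD, n = 7) to -0.12 ± 0.43 (n = 6), a difference of 6.31 ± 0.45 (SE; 79.6-fold; adjusted p = 1.58e-12). Cstdc6, a cystatin, rose by 5.60 ± 0.43, Ahsg, the plasma protein fetuin-A, by 5.57 ± 0.74 and F2, prothrombin, by 5.28 ± 0.50. All 17 liver genes rose (median 3.74, adjusted p = 3.87e-16, and 0.0356 with an estimated correlation). Kng1, Igfbp1, Hpx and Apoa2 were among them or ranked with them, but their control signal at 4 weeks was not well above background on any array and no fold is given. H2-D1, a classical class I gene, went from 0.22 ± 0.19 to -2.54 ± 0.39, a fall to a 6.77-fold lower ratio (adjusted p = 7.96e-14), and Cd74, the class II invariant chain, fell 5.63-fold, from 0.17 ± 0.16 to -2.32 ± 0.16.

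Of 33 MHC genes 23 fell and 3 rose (median -1.39), with H2-T23 at -2.44 ± 0.15 (SE). Of 26 T cell genes 16 fell and none rose, among them the chromatin organiser Satb1 (-1.57 ± 0.19) and the cytoplasmic kinase Zap70 (-1.53 ± 0.19). B cell genes fell for 11 of 25 and rose for 2, with Fcmr, the IgM Fc receptor, at -1.60 ± 0.15 and the kinase Blk at -2.98 ± 0.35. Neutrophil genes rose for 13 of 19 (S100a8 3.50 ± 0.55, S100a9 3.49 ± 0.49, Ms4a3 2.37 ± 0.36) and oxidative phosphorylation genes for 25 of 42, with 5 lower (Cox7b 2.11 ± 0.21, Ndufb3 1.94 ± 0.15). Epithelium and duct genes rose for 9 of 24, with 1 lower. Falls were also found for 14 of 46 cell cycle, 13 of 24 blood endothelium, 8 of 17 circadian clock and 10 of 24 immediate early genes, against 1, 2, 1 and 3 rises. Further large falls were Dusp8, a MAP kinase phosphatase (-4.65 ± 0.46), Sbno2 (-3.44 ± 0.26), Srrt (-3.17 ± 0.34), the clock gene Per1 (-3.10 ± 0.32) and Znfx1 (-3.09 ± 0.40).

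In total 9637 genes passed between 4 weeks and 10 days, 4450 higher and 5187 lower, and 5052 genes had groups that did not overlap, where chance gives 0.117% of genes. With scan day as a random block 6301 passed, with the Feature Extraction version as a block 4153 and with the scanner as a block 2343, and 3 of the 11 lists lost the call with either of the last 2, and the circadian clock and immediate early lists with acinar and islet scores as covariates. The scanner that read all 4 week arrays read no other array than replicate 2 at 8 weeks. The scanner-adjusted differences from 4 weeks, here and below, therefore rest on that array. Among the 4028 that changed by at least 1, a median share of 0.758 of the change lay in the control channel (quartiles 0.283 to 1.16). In the NOD channel alone Afp was at -1.01, H2-D1 at 0.24, Cd74 at 1.12 and S100a8 at -0.27, and 20 of the 37 genes followed for this pair of ages turned direction and 9 lost the call, as did 6 and 4 of the 11 lists. The NOD signal was well above background on 3 of 6 arrays at 4 weeks for Blk and Znfx1, on 5 for Dusp8 and Srrt, and on 6 of 7 at 10 days for F2. The control signal was so on 4 of 6 at 4 weeks for Cstdc6, and that of Sbno2 on 5 of 7 at 10 days in both channels. The 11 lists together held 76 rises and 101 falls over all genes tested, and 78 and 107 adjusted over the list alone. Of 1969 genes with several probes past the threshold, 28.3% had probes of opposite direction.

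From 4 to 8 weeks the ratios of MHC, cell cycle and erythroid genes rose. The 12 lists that passed lost the call with an estimated correlation (adjusted p from 0.483 to 0.791). Cd74 went from -2.32 ± 0.16 (SD, n = 6) to 0.35 ± 0.43 (n = 4), 6.40-fold higher (adjusted p = 4.93e-12). Of 33 MHC genes 21 rose and 3 fell (median 0.97), with H2-DMb2 at 2.23 ± 0.20 (SE) and H2-D1 at 2.01 ± 0.19. Cell cycle genes rose for 33 of 46 (median 0.96), among them Uhrf1, a DNA methylation maintenance factor (2.50 ± 0.27), and Espl1, separase (1.85 ± 0.28). Erythroid genes rose for 14 of 19 (median 1.88), with the transcription factor Klf1 at 3.14 ± 0.55, the globin gene Hba-a1 at 2.96 ± 0.52 and Epb42 at 2.90 ± 0.50. B cell genes rose for 14 of 25 and fell for 2 (Fcmr 1.92 ± 0.17, Cd22 1.87 ± 0.22), and heat shock and unfolded protein genes rose for 10 of 23 and fell for 2 (Pdia4 2.22 ± 0.25, Calr 2.10 ± 0.18).

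Islet genes fell for 12 of 23 and rose for 2. Gcg and G6pc2 were among the falls, but the control signal of both at 4 weeks was not well above background on any array. Reticular stroma genes rose for 14 of 38 and fell for 5, blood endothelium genes for 7 of 24 and fell for 2, and immediate early genes for 8 of 24 and fell for 2. Epithelium and duct genes fell for 7 of 24 and rose for 1, oxidative phosphorylation genes for 17 of 42 and rose for 5, and ribosomal protein genes for 18 of 62 and rose for 7. Among genes with a symbol whose groups did not overlap, the largest falls were Klk1b11, a kallikrein (-5.72 ± 1.01), Sostdc1 (-4.38 ± 0.90), the non-coding RNA Rmrp (-4.10 ± 0.51) and Tspan1 (-3.98 ± 0.68), and Srrt rose by 3.28 ± 0.39. Pkdcc also rose, with a control signal at 8 weeks not well above background.

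Between 8 and 4 weeks 7666 genes passed, 4239 higher and 3427 lower, or 4308 with the Feature Extraction version and 3216 with the scanner as a block, and 3 of the 12 lists lost the call with each. With acinar and islet scores as covariates the islet test turned upward and epithelium, reticular stroma, blood endothelium and immediate early lists lost the call. A median share of 0.850 of the changes of at least 1 lay in the control channel (quartiles 0.329 to 1.23). In the NOD channel alone Cd74 was at -0.16, Klf1 at -1.70, Hba-a1 at -1.15 and Uhrf1 at 0.01, and 10 of the 20 genes followed turned direction and 9 lost the call, as did 7 and 5 of the 12 lists. The control signal was well above background on 1 of 6 arrays at 4 weeks for Tspan1, 2 for Klk1b11 and 5 for Sostdc1. At 8 weeks it was so on 1 of 4 for Epb42, 2 for Srrt and 3 for Espl1. The NOD signal was so on 3 of 4 at 8 weeks for Epb42 and Sostdc1 and on 5 of 6 at 4 weeks for Srrt. Members of the 12 lists made 136 rises and 70 falls over all genes tested, and 150 and 77 adjusted over the list alone.

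From 8 to 12 weeks the ratios of erythroid, neutrophil, mitochondrial and cell cycle genes fell. All 12 lists that passed lost the call with an estimated correlation (adjusted p from 0.211 to 0.759). Eraf went from -0.09 ± 1.20 (SD, n = 4) to -4.16 ± 1.36 (n = 7), 16.8-fold lower (adjusted p = 0.000169), and 17 of 19 erythroid genes fell (median -2.27), among them Klf1 (-3.19 ± 0.53, SE) and Hba-a1 (-3.11 ± 0.50). The globin gene Hbb-bt fell by 3.57 ± 0.58 (control signal saturated on 6 of 7 arrays and NOD signal on 1 at 12 weeks) and Redrum, an erythroid non-coding RNA, was at -3.41 ± 0.61. Neutrophil genes fell for 9 of 19, with S100a8 at -3.18 ± 0.62 and Camp, the cathelicidin precursor, at -3.60 ± 0.63. Oxidative phosphorylation genes fell for 29 of 42 (median -0.79; Atp5o -1.47 ± 0.25, Ndufa9 -1.07 ± 0.17) and cell cycle genes for 22 of 46 (Ccna2 -1.62 ± 0.32, Tyms -1.61 ± 0.25). Ribosomal protein genes fell for 22 of 62, with 1 higher, and heat shock genes for 8 of 23 (Sdf2l1 -2.03 ± 0.27, Hspe1 -1.48 ± 0.21).

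Lymphatic endothelium genes rose for 3 of 13, including the hyaluronan receptor Lyve1 (1.82 ± 0.28), circadian clock genes for 5 of 17, and immediate early genes for 7 of 24. Diabetes susceptibility candidates rose for 5 of 22, including Ptpn22, a lymphocyte phosphatase (1.39 ± 0.22), and Ctla4, an inhibitory T cell receptor (1.27 ± 0.29). B cell genes fell for 7 of 25 and rose for 3. The acinar list fell as a set (median -3.31, adjusted p = 3.05e-06, and 0.759 with an estimated correlation), but 1 of its 29 genes passed, Amy2, pancreatic amylase (adjusted p = 0.0442; control signal saturated on 4 of 4 arrays at 8 weeks and 6 of 7 at 12 weeks), and 0 adjusted over the list alone. The median was -3.34 over the 6 acinar genes without saturated signals at 16 and 20 weeks. Cirbp, an RNA-binding protein, rose by 2.66 ± 0.35, and Galnt15, Acot1 and Lrp5 by 2.32 ± 0.47, 2.21 ± 0.57 and 2.13 ± 0.35.

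Between 12 and 8 weeks 3423 genes passed, 1304 higher and 2119 lower, or 1588 and 1670 with each array centred on its median, and the median share in the control channel was 0.376 (quartiles -0.073 to 0.726). Without replicates 5 and 6 at 12 weeks 5312 genes passed, with the Feature Extraction version as a block 1985, and with the scanner as a block 1804, and in each of these 3 settings 3 of the 12 lists lost the call, the diabetes candidates every time, and with acinar and islet scores as covariates the acinar list turned direction (0.10). Without replicate 4 at 8 weeks 2255 genes passed. In the NOD channel alone Klf1 was at 0.18 and Ptpn22 at -0.25, and 9 of the 21 genes followed lost the call, Eraf (-1.34) and Hba-a1 (-0.52) among them. The cell cycle (0.17), B cell (0.53) and ribosomal protein (0.059) lists turned direction there and 6 of the 12 lists lost the call, among them erythroid and neutrophil genes. The control signal of Ctla4 was well above background on 1 of 7 arrays at 12 weeks, and the NOD signal of Klf1 and Redrum on 6. Members of the 12 lists made 24 rises and 115 falls over all genes tested, and 26 and 138 adjusted over the list alone.

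From 12 to 16 weeks ribosomal protein, mitochondrial and MHC genes rose. With an estimated correlation each of the 7 lists that passed had an adjusted p of 0.985. Rps15a, a ribosomal protein gene, went from -1.78 ± 0.93 (SD, n = 6) to 0.99 ± 0.20 (n = 6), 6.83-fold higher (adjusted p = 8.80e-09). Of 62 ribosomal protein genes, of which 23 had a saturated signal on some array in the NOD channel and 20 in the control channel, 28 rose and 2 fell (median 0.42), among them Rpl36 (1.66 ± 0.27, SE) and Rpl29 (1.39 ± 0.20). Oxidative phosphorylation genes rose for 21 of 42 and fell for 1 (Ndufb8 1.70 ± 0.26, Cox5b 1.61 ± 0.25), and MHC genes rose for 11 of 33 and fell for 3 (H2-DMb2 1.40 ± 0.18, Cd74 1.36 ± 0.16). B cell genes rose for 10 of 25 and fell for 3, with Fcer2a, the low-affinity IgE receptor CD23, at 1.46 ± 0.19 and Fcmr at 1.32 ± 0.15. Blood endothelium genes rose for 8 of 24 and fell for 1, with Madcam1, a mucosal addressin, at 1.22 ± 0.21 and Plvap at 1.03 ± 0.13.

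Reticular stroma genes rose for 5 of 38, including Col6a1 (2.09 ± 0.32), and epithelium and duct genes fell for 4 of 24. Tmsb10 rose by 2.77 ± 0.34, Lgals1, galectin-1, by 2.21 ± 0.29 and Tyrobp, a myeloid and NK cell adaptor, by 2.16 ± 0.28. Lars2, a mitochondrial leucyl-tRNA synthetase, fell as well, with a control signal saturated on every array of both ages. The receptor P2ry10 fell by 2.28 ± 0.27, Ptpn22 by 2.19 ± 0.20 and Heatr5a by 2.12 ± 0.28. In total 4676 genes passed, 2654 higher and 2022 lower, with a median share of 0.0542 in the control channel (quartiles -0.079 to 0.232). Within the scan day shared by these ages 3025 passed (1781 and 1244), where the 7 lists kept their direction and 6 of them the call, and the reticular stroma list, at 0.36, lost it. With scan day as a block 4284 genes passed and the 7 lists kept the call. Without replicates 5 and 6 at 12 weeks 3 of the 7 lost the call, and with acinar and islet scores as covariates the reticular stroma and blood endothelium lists did. There were 2772 genes past the threshold in the NOD channel alone, where Fcer2a and 3 of the 7 lists lost the call and the reticular stroma list turned direction (-0.14). The control signal of Col6a1 was well above background on 5 of 7 arrays at 12 weeks and 2 of 6 at 16 weeks. Members of the 7 lists made 83 rises and 14 falls over all genes tested, and 99 and 18 adjusted over the list alone.

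From 16 to 20 weeks pancreatic, erythroid and neutrophil genes rose and lymphocyte, stromal and endothelial genes fell. Of the 21 lists that passed, 15 lost the call with an estimated correlation (adjusted p from 0.0872 to 0.649), and the islet, erythroid, neutrophil, B cell, heat shock (0.0450) and glucocorticoid response (0.0435) lists held. Among genes with a symbol whose groups did not overlap, the largest rises were Reg2 (adjusted p = 0.00115), whose control signal at 16 weeks was saturated on all 6 arrays, Reg3a, from -6.81 ± 1.07 (SD, n = 6) to 1.26 ± 1.45 (n = 5), 269-fold (adjusted p = 0.000205), Reg3b (7.49 ± 1.71, SE), Ins1 (6.07 ± 1.003) and Gcg (5.67 ± 0.87). Islet genes rose for 10 of 23 and for 11 adjusted over the list alone (adjusted p = 1.69e-10, and 0.0450 with an estimated correlation), with the hormone gene Sst at 3.31 ± 0.49 and Chga, chromogranin A, at 4.67 ± 0.81. The acinar list rose as a set (median 3.75, adjusted p = 6.02e-13, and 0.238 with an estimated correlation), with 2 of 29 genes past the threshold over all genes tested and 17 adjusted over the list alone, and the median was 3.92 over the 6 of them without saturated signals. Gp2, the zymogen granule glycoprotein, rose by 4.49 ± 1.45, and Cel, bile salt lipase, did not pass (adjusted p = 0.0661), with a control signal saturated on every array of both ages.

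Erythroid genes rose for 18 of 19 (median 2.68, adjusted p = 6.56e-26, and 0.0410 with an estimated correlation), among them Trim10 (3.51 ± 0.49), Alas2, the erythroid haem synthesis enzyme (3.31 ± 0.51), and Klf1 (3.08 ± 0.51). Neutrophil genes rose for 12 of 19 (median 1.80, adjusted p = 3.83e-17, and 0.0410 with an estimated correlation), with Camp at 4.16 ± 0.60, S100a8 at 3.92 ± 0.59 and Ctsg, cathepsin G, at 3.07 ± 0.48. Spleen red pulp genes rose beside them for 2 of 12, including Cd5l, a macrophage-secreted protein (2.09 ± 0.34, adjusted p of the list 0.0258, and 0.238 with an estimated correlation). Cell cycle genes rose for 12 of 46 (Mki67 1.81 ± 0.36, Ube2c 1.74 ± 0.34) and heat shock genes for 6 of 23 (Herpud1 1.48 ± 0.30). Glucocorticoid response genes rose for 5 of 14 (Ddit4 1.54 ± 0.31, and Lcn2, with a control signal not well above background on any array at 20 weeks), epithelium and duct genes for 6 of 24 and oxidative phosphorylation genes for 2 of 42.

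B cell genes fell for 9 of 25 (adjusted p = 1.87e-10, and 0.0410 with an estimated correlation), with the transcription factor Bcl11a at -1.64 ± 0.31 and Fcer2a at -1.41 ± 0.21. T cell genes fell for 9 of 26 (Bcl11b -1.15 ± 0.22, Tcf7 -0.74 ± 0.18). MHC genes fell for 15 of 33 and rose for 1 (H2-Q8 -0.82 ± 0.18). Falls were also found for 14 of 38 reticular stroma genes (Col6a1 -1.85 ± 0.35, Col3a1 -1.68 ± 0.47) and 10 of 24 blood endothelium genes, with 1 higher (Glycam1, a ligand of L-selectin on high endothelial venules, -1.63 ± 0.25, Madcam1 -1.21 ± 0.23). Type I interferon genes fell for 7 of 31 and rose for 2 (Ifit3 -1.47 ± 0.40, Dhx58 -1.28 ± 0.23), and interferon gamma genes fell for 4 of 22 and rose for 1. Adipocyte genes fell for 4 of 21 (Fasn, fatty acid synthase, -2.18 ± 0.36, Dgat2 -2.28 ± 0.41, Me1 -1.93 ± 0.52). Dendritic cell genes fell for 5 of 25, chemokines and receptors for 6 of 46 and cytotoxic lymphocyte genes for 2 of 25. The Wnt receptor Fzd10 fell too (adjusted p = 0.000189), with a control signal not well above background at either age.

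Between 20 and 16 weeks 2469 genes passed, 1053 higher and 1416 lower, and 2010 had groups that did not overlap, where chance gives 0.433% of genes. Within the shared scan day 1479 passed (750 and 729), with scan day as a block 2572, and all 21 lists kept direction and call in both. Every array of both ages was scanned on that day, so these fits could change only the estimated spread, not the differences. With the acinar and islet scores of each array as covariates 9 genes passed, 39 of the 48 genes followed and 8 of the 21 lists lost the call and 2 lists turned direction (acinar and oxidative phosphorylation). The islet scores did not overlap between 16 weeks (-2.65 to -1.57) and 20 weeks (-0.65 to 0.23). This covariate can therefore take up a difference between these ages of any source, so the lost calls do not point to the pancreas. As for the NOD channel alone, 143 genes passed, and there 29 of the 48 genes followed and 3 of the 21 lists lost the call. Without replicate 3 at 20 weeks 1402 genes passed. The median share in the control channel was 0.280 (quartiles 0.136 to 0.427). The NOD signal was well above background at 16 weeks on 3 of 6 arrays for Sst, 4 for Reg3a, Gcg and Chga and 5 for Reg2, Reg3b and Ins1. The control signal was so on 4 of 5 at 20 weeks for Sst, and for Col6a1 on 2 of 6 at 16 weeks and 1 of 5 at 20 weeks, where its NOD signal was so on 3. Members of the 21 lists made 80 rises and 85 falls over all genes tested, and 122 and 123 adjusted over the list alone.

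Set against 4 weeks, nodes at 20 weeks had higher ratios of erythroid, MHC, macrophage and cell cycle genes. The 9 lists that passed lost the call with an estimated correlation (adjusted p from 0.677 to 0.757). Cd74 went from -2.32 ± 0.16 (SD, n = 6) to 1.29 ± 0.26 (n = 5), 12.2-fold higher (adjusted p = 9.02e-17). Of 33 MHC genes 19 rose and 2 fell, including H2-DMb2 (2.03 ± 0.19, SE). Erythroid genes rose for 17 of 19 (Trim10 4.18 ± 0.49, Hba-a1 4.17 ± 0.49 with a NOD signal saturated on 2 of 5 arrays at 20 weeks, Klf1 3.86 ± 0.51) and cell cycle genes for 27 of 46 with 1 lower. Macrophage genes rose for 11 of 26 (C1qa, a complement component, 2.54 ± 0.28, and the growth factor receptor Csf1r 1.76 ± 0.18). Circadian clock genes rose for 8 of 17 and fell for 1 (Per1 3.82 ± 0.34, Dbp 2.20 ± 0.27) and immediate early genes for 10 of 24 and fell for 2. Glucocorticoid response genes rose for 7 of 14 and fell for 2, with Tsc22d3, a glucocorticoid-induced leucine zipper, at 2.46 ± 0.29. Type I interferon genes fell for 17 of 31 and rose for 3 (Rtp4 -2.89 ± 0.33, Ifit3 -2.12 ± 0.40). Oxidative phosphorylation genes fell for 22 of 42 and rose for 9 (Ndufb3 -2.19 ± 0.17, Cox6c -1.82 ± 0.17).

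Dusp8 rose by 4.65 ± 0.50, Ppp1r14c by 4.39 ± 0.94 and Mta2, a chromatin remodelling subunit, by 4.25 ± 0.19, and the metallothionein Mt2 fell by 4.42 ± 0.91 and Rmrp by 4.24 ± 0.48. Between 20 and 4 weeks 9946 genes passed, 4575 higher and 5371 lower, against a median shift of all genes of -0.12, and a median share of 0.496 lay in the control channel. With the scanner as a block 3475 passed and 4 of the 9 lists lost the call, and 33.5% of 2106 genes with several probes past the threshold had probes of opposite direction. Mt2 stood at 0.73 and the oxidative phosphorylation list at 0.12 in the NOD channel alone, and 4 of the 19 genes followed and 2 of the 9 lists lost the call. The control signal of Ppp1r14c was well above background on 2 of 5 arrays at 20 weeks, and the NOD signal of Dusp8 on 5 of 6 at 4 weeks. Members of the 9 lists made 111 rises and 47 falls over all genes tested, and 118 and 49 adjusted over the list alone.

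Set against 10 days, nodes at 20 weeks had higher ratios of liver-secreted protein, neutrophil and erythroid genes and lower ratios of T cell and MHC genes. Apart from the liver list, the 14 other lists that passed lost the call with an estimated correlation (adjusted p from 0.188 to 0.571). Afp went from -6.44 ± 1.57 (SD, n = 7) to -0.85 ± 0.51 (n = 5), 48.2-fold higher (adjusted p = 1.56e-09). Of 17 liver genes 16 rose (median 3.21, adjusted p = 1.55e-25, and 0.00269 with an estimated correlation), including the fibrinogen chains Fgg (5.16 ± 0.71, SE) and Fgb (4.40 ± 0.53). Ambp rose by 4.96 ± 0.90. Kng1, Mbl2 and Apoa2 had control signals at 20 weeks not well above background. Neutrophil genes rose for 14 of 19 (Camp 3.76 ± 0.58, Ngp 3.22 ± 0.43) and erythroid genes for 13 of 19 (Hba-a1 2.95 ± 0.47 with saturated signals on 2 of 7 control spots at 10 days and 2 of 5 NOD spots at 20 weeks, Epb42 2.63 ± 0.45). Cell cycle genes rose for 12 of 46 with 1 lower (Ccne2 1.79 ± 0.27), macrophage genes for 7 of 26 with 1 lower (Fcgr3 1.19 ± 0.21) and spleen red pulp genes for 3 of 12 (Cd5l 2.15 ± 0.33).

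T cell genes fell for 17 of 26 (the interleukin-7 receptor Il7r -1.54 ± 0.18, Bcl11b -1.21 ± 0.22), and B cell genes for 8 of 25 with 1 higher. MHC genes fell for 16 of 33 with 2 higher (H2-M3 -1.48 ± 0.17, H2-M2 -1.42 ± 0.15, H2-D1 -1.27 ± 0.17). Regulatory T cell genes fell for 3 of 15 with 1 higher, among the falls Ikzf2 (-1.69 ± 0.29) and Gpr83 (-1.03 ± 0.15). Mast cell, basophil and eosinophil genes rose for 4 of 19 and fell for 1 (Ear1 2.19 ± 0.44), heat shock genes for 4 of 23, immediate early genes for 4 of 24 and epithelium and duct genes for 4 of 24 with 1 lower. The acinar list rose as a set (median 2.83, or 1.65 over the 6 genes without saturated signals at 16 and 20 weeks; adjusted p = 9.45e-06, and 0.571 with an estimated correlation), with 2 of 29 genes past the threshold over all genes tested and 0 adjusted over the list alone. Sorl1, a sorting receptor, fell by 2.53 ± 0.19, the nuclear import factor Ipo7 by 2.50 ± 0.35 and the splicing factor Tra2b by 2.23 ± 0.21.

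Between 20 weeks and 10 days 4879 genes passed, 1854 higher and 3025 lower against a median shift of all genes of -0.10, or 2552 and 1959 with each array centred on its median. With scan day as a random block 2551 passed and with the Feature Extraction version as a block 1276, and 2 of the 15 lists lost the call with the latter. With acinar and islet scores as covariates the acinar, epithelium, regulatory T cell and heat shock lists lost it. A median share of 0.446 lay in the control channel (quartiles -0.023 to 0.937), and in the NOD channel alone Afp was at -1.21 and H2-D1 at 1.12, and 10 of the 26 genes followed turned direction and 8 lost the call, as did 6 and 4 of the 15 lists. At 20 weeks the control signal was well above background on 1 of 5 arrays for Fgg, Fgb and Ccne2 and 2 for Epb42, and the NOD signal on 1 for Fgg, 2 for Afp and 3 for Fgb. The 15 lists made 87 rises and 48 falls over all genes tested, and 95 and 57 adjusted over the list alone.

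Genes that regulate or encode self antigens and immune effectors were followed at every age. Deaf1, a transcription factor with a role in peripheral antigen expression, had a ratio of -1.71 ± 1.15 (SD, n = 6) at 10 days, 1.43 ± 2.50 (n = 6) at 4 weeks, and -1.77 ± 2.87 (n = 4) at 8 weeks on its brightest probe, where the mean was 0.83 without replicate 2 and 2.15 without replicate 5 at 4 weeks, and -0.36 without replicate 2 at 8 weeks. This probe stood at -4.42 ± 1.66 (n = 7; NOD signal well above background on 4) at 12 weeks, -3.61 ± 2.04 (n = 6) at 16 weeks and 0.00 ± 1.38 (n = 5) at 20 weeks (adjusted p = 7.87e-06 against the control at 12 weeks and 0.000283 at 16 weeks). It rose between 16 and 20 weeks (3.61 ± 1.12, SE; adjusted p = 0.0395) and between 10 days and 4 weeks (3.14 ± 1.07; adjusted p = 0.0223). The other Deaf1 probes stood at 0.14 ± 0.31 (SD, n = 7) and 0.23 ± 0.45 (n = 7) at 12 weeks. With the dimmer but always detected probe the difference between 4 weeks and 10 days was -0.99. The call between 16 and 20 weeks was lost with the acinar and islet scores as covariates and both calls in the NOD channel alone. Since the islet score by itself separates 16 from 20 weeks, the loss with the covariates does not show the source.

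Ins1 and Ins2, which encode insulin, had ratios of -4.93 ± 1.79 (SD, n = 7; NOD signal well above background on 3) and -5.85 ± 2.07 (n = 7) at 12 weeks and of 1.46 ± 1.66 (n = 5) and 0.66 ± 2.38 (n = 5) at 20 weeks. The Ins2 mean at 20 weeks was 1.70 without replicate 3, 0.27 without replicate 1, 0.37 without replicate 2 and 0.36 without replicate 5. Ins2 rose by 6.79 ± 1.25 (SE) from 16 to 20 weeks. With the NOD channel alone the rises of Ins2 (3.75, adjusted p = 0.172) and Ins1 (3.28, adjusted p = 0.112) lost the call. They also did with acinar and islet scores as covariates, of which the islet score by itself separates 16 from 20 weeks. Aire, the thymic regulator of self antigens, was at -0.70 ± 0.66 (SD, n = 6) at 4 weeks and 0.79 ± 0.29 (n = 6) at 16 weeks. It fell between 10 days and 4 weeks (-0.78 ± 0.21, SE; adjusted p = 0.00323), but stood at 0.10 in the NOD channel alone. Ctla4 was higher than the control at 12 weeks (1.01 ± 0.54, SD, n = 7; control signal well above background on 1; adjusted p = 2.51e-05), and Ifng, interferon gamma, at 4 weeks (1.15 ± 0.29, n = 6; NOD signal well above background on 5 and control signal on 4; adjusted p = 5.08e-05), where another Ifng probe stood at 0.37 ± 0.61 (n = 6). At 16 weeks the 2 Ifng probes stood at -0.36 ± 0.83 (-0.030 without replicate 5) and 0.70 ± 0.48. Foxp3, the regulatory T cell factor, differed between 20 weeks and 10 days by -0.88 ± 0.31 (SE; adjusted p = 0.0464), a call lost in 6 other settings, among them arrays centred on their median, and the difference was 0.71 in the NOD channel alone. Both its signals were well above background on 3 of 5 arrays at 20 weeks, and its control signal on 5 of 7 at 10 days. Foxp3 also rose between 8 and 12 weeks (1.15 ± 0.33; adjusted p = 0.0182) and fell between 10 days and 4 weeks (-0.80 ± 0.29; adjusted p = 0.0341). Its NOD signal was well above background on 5 of 7 arrays at 12 weeks and 4 of 6 at 4 weeks. Il2 did not pass the test among the ages (adjusted p = 0.192), nor did the class II gene H2-Aa on its brightest probe (adjusted p = 0.0719). Another H2-Aa probe stood at -2.85 ± 0.44 (SD, n = 6) at 4 weeks where the brightest was at 0.04 ± 0.48 (n = 6). H2-Ab1 and H2-Eb1 fell between 10 days and 4 weeks by 1.80 ± 0.15 and 1.67 ± 0.22 (SE), and H2-K1 by 1.19 ± 0.25 (NOD signal saturated on 1 array of each age). H2-Ab1 and H2-Eb1 turned direction in the NOD channel alone (0.80 and 0.67), and with the Feature Extraction version as a block H2-K1 lost the call. Between 16 and 20 weeks H2-Ab1 and H2-D1 fell by 0.59 ± 0.16 and 0.55 ± 0.18, calls lost in the NOD channel alone, and for H2-D1 also with arrays centred on their median.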

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

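Of the tests below, only the share of the change carried by the control channel between 4 weeks and 10 days was set before its result was seen, and all others, the counts of splits included, were chosen after.

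In 24 of 284 groups of arrays 1 array lay far from the rest of its age, where chance gives about 1 in 20. The acinar score of replicate 2 at 8 weeks was -6.16 (others -0.34 to 0.51), and the mean of that age, -1.43, was 0.15 without it. Insulin genes stood apart on 3 arrays: Ins1 and Ins2 at -1.04 and -1.40 on replicate 6 at 12 weeks and -1.47 and -2.04 on replicate 5 at 16 weeks, all above the others, and Ins2 at -3.54 on replicate 3 at 20 weeks, below them. Liver scores were -1.40 on replicate 3 at 10 days, 0.086 on replicate 6 at 16 weeks and 0.92 on replicate 1 at 20 weeks, each the highest of its age. The type I interferon score was 0.95 on replicate 5 at 12 weeks (others to 0.09) and the interferon gamma score -0.10 on replicate 6 at 12 weeks (others from 0.19). Il2 was at -1.84 on replicate 3 at 10 days and Ifng at -1.98 on replicate 5 at 16 weeks. Other single scores were adipocytes 0.22 and lymphocyte precursors -0.32 (replicate 1 at 8 weeks), macrophages -0.37 (replicate 2 at 8 weeks), regulatory T cells -0.41 (replicate 4 at 8 weeks), epithelium 0.46 (replicate 2 at 12 weeks) and cytotoxic lymphocytes 0.42 (replicate 3 at 4 weeks). The last ones were spleen red pulp -0.32 (replicate 2 at 10 days), circadian clock 0.67 (replicate 3 at 20 weeks), ribosomal proteins -0.13 (replicate 5 at 4 weeks), oxidative phosphorylation -0.27 (replicate 1 at 20 weeks) and diabetes candidates 0.22 (replicate 7 at 10 days).

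The ratio to the control differed between ages for 9637 genes between 4 weeks and 10 days, 7666 between 8 and 4 weeks, 3423 between 12 and 8 weeks, 4676 between 16 and 12 weeks, 2469 between 20 and 16 weeks, 9946 between 20 and 4 weeks and 4879 between 20 weeks and 10 days. Other splits were counted over the 22835 genes with a value on every array, with 100 splits for each count, the real one included. The real split alone reached its count (1 of 100) in each of the 7 comparisons, with real values against the highest other of 7544 and 2535, 5913 and 4118, 2548 and 2230, 3476 and 3047, 1969 and 1190, 7781 and 4076, and 3829 and 660, in the order above. The same held among the 6 ages (12117 and 138), among 4 to 20 weeks (11257 and 938), in the control channel (15513 and 3559) and in the NOD channel (14028 and 73). No other split drawn gave as many genes, but 1 of 100 is the smallest share that 100 splits can give. These counts were not adjusted for their number either. The splits exchange arrays, which may not be separate animals, and cannot exclude chance between animals or an effect of scan day. For list counts, 3 of 100 splits gave as many between 20 and 16 weeks (20 lists, highest other 20). This was the smallest of the 7 list results, which were not adjusted for their number, so chance cannot be excluded there. Nor can it be in the other comparisons. There 12 (real 11, highest other 14), 12 (11 and 16), 16 (12 and 15), 73 (5 and 13), 34 (8 and 14) and 28 (11 and 17) of 100 splits gave as many, in the order above.

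Pancreatic acinar and islet genes had higher ratios at 20 weeks than at 16 weeks. For the 6 acinar genes without a saturated signal at these ages the control channel carried 0.161 of the change (0.0892 to 0.218 by gene). This argues against a different control RNA as the main source of the change of those genes. For the acinar list as a whole the share was 0.0802, but 23 of 29 genes had a saturated control signal, so a different control RNA stays open for the rest. Pancreatic tissue carried over with some nodes may account for the acinar part, since within ages the NOD signals of the 29 acinar genes moved together (median pairwise r = 0.950, quartiles 0.921 to 0.971, across arrays, and 0.954 for the 6 genes above), while for islet genes that value was 0.238. For the islet list the control channel itself differed, at 9.41 ± 0.22 (SD, n = 6) at 16 weeks and 8.40 ± 0.12 (n = 5) at 20 weeks. It carried 0.539 of the change of the islet ratio, and a different control RNA may account for that share. A rise of tissue-restricted genes of many organs also stays open, since the skeletal muscle list (median difference -0.41) had 2 of 15 genes well above background in both channels on every array at 16 and 20 weeks, and the liver list stood at 0.49. A change in the pancreas or node with age stays open and was not tested.

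Liver-secreted protein genes had lower ratios at 10 days than at other ages, and many genes differed between 4 weeks and 10 days. The NOD liver score at 10 days lay above the mean of the other ages by 1.13 (SD 1.04), so it gave no sign of less liver RNA in the NOD nodes. It cannot settle this, because scan day and age cannot be told apart at 10 days. A control RNA with liver transcripts on the 10 day arrays may account for the low ratios, since the control liver score there was 4.25 above that of the next age, and for the wider change the control channel carried a median share of 0.758 (quartiles 0.283 to 1.16). Differences of single probes on the 4 week arrays also stay open, as 28.3% of genes with several probes past the threshold had probes of opposite direction against 4.64% between 20 and 16 weeks (Fisher's exact test, two-sided, p = 4.05e-19). The share of 4.64% was the lowest of all comparisons. It was 24.5% between 8 and 4 weeks and 33.5% between 20 and 4 weeks. Without 4 week arrays it reached 9.80% (12 and 8 weeks), 16.5% (16 and 12 weeks) and 19.1% (20 weeks and 10 days), so opposite probes were not particular to 4 weeks. A difference of age, in either strain, stays open and was not tested.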

How the results depend on the processing

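The scanner block, the fit within 1 scan day, the acinar and islet covariates, the fit without replicates 5 and 6 at 12 weeks and all alternatives for the counts of the control and the NOD channel across ages and for the MHC region were chosen after seeing the data, and the other alternatives before the data were examined. Of 213 values of named genes, 209 kept direction and call with each array centred on its median, 212 with the deposited values, 208 after normexp background correction, 208 with scan day as a random block, 204 with the Feature Extraction version and 196 with the scanner as a block. Of 100 list results 97, 96, 89, 98, 88 and 85 did so, in the same order. With acinar and islet scores as covariates 162 gene values and 70 list results did so, 50 and 22 lost the call, and 8 lists turned direction. Among probes well above background in both channels on all arrays 58 list results did so and 35 lost the call. Leaving out each array in turn left 7343 gene results as they were, ended the call of 97 and added the call of 15, and left 3414 list results as they were and ended the call of 86. Signal over background limits the ratios: from 42.1% to 93.5% of probes in the NOD channel and from 36.3% to 90.2% in the control channel were well above background on an array, and a ratio of a dimmer probe is only a bound. The cause of the changes below was not tested, except where it is named.

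Without any filter on dim probes, with all probes, with scan day as a fixed block and with arrays centred, every total stayed within 1.5 times the reported one. Of their parts, genes higher at 20 weeks (468) and lower between 20 weeks and 10 days (1959) with arrays centred, and probes lower at 4 weeks with all probes (2820), did not. By the labels, the only link between single arrays of different ages is the replicate number. Of 77 pairs with the same number at different ages 4 had deviations that correlated above 0.1 (median r = 0.011), against 39 of 430 pairs with different numbers (median -0.0042), and 3 arrays correlated best with their own number. With the replicate block 8923 genes passed between 4 weeks and 10 days, 2064 between 20 and 16 weeks and 91 list shifts, and no count moved by more than 1.5 times.

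Normexp background correction with loess gave strain counts of 164 at 10 days, 536 at 4 weeks, 40 at 8 weeks, 451 at 12 weeks, 524 at 16 weeks and 157 at 20 weeks, and 1 gene at every age. The split at 20 weeks was 69 higher and 88 lower, and 3129 and 2889 between 20 weeks and 10 days. In the deposited values 170 genes passed at 8 weeks (55 higher and 115 lower), where spots with a surrogate signal stand at 0. Among genes well above background in both channels on all 35 arrays, which are fewer, the strain counts were 84, 1078, 46, 698, 924 and 457, with 0 at every age and 0 in the MHC region (Fisher's exact test, p = 1). In that set 8407 and 8241 genes differed among the 6 ages and among 4 to 20 weeks, 8461 in the control channel and 8103 in the NOD channel, 5507 genes passed between 4 weeks and 10 days, 4976 between 8 and 4 weeks and 6094 between 20 and 4 weeks, and 51 list shifts and 7 mean-ratio lists passed. Another probe then stood for Klf2, at -0.72, and for Deaf1, at -0.99 between 4 weeks and 10 days.

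With the Feature Extraction version as a block 148 genes passed against the control at 8 weeks, 4153 between 4 weeks and 10 days, 4308 between 8 and 4 weeks, 1985 between 12 and 8 weeks and 1276 between 20 weeks and 10 days. The scanner block gave 2 genes at every age, 10137 among the 6 ages, 8949 among 4 to 20 weeks, 2343 between 4 weeks and 10 days, 3216 between 8 and 4 weeks, 1804 between 12 and 8 weeks and 3475 between 20 and 4 weeks. Its differences from 4 weeks rest on replicate 2 at 8 weeks, the only other array read on the scanner of the 4 week arrays. Scan day as a random block (consensus correlation 0.0817) gave 139 at 8 weeks, 6301 between 4 weeks and 10 days, 2147 between 12 and 8 weeks and 2551 between 20 weeks and 10 days. Within the 1 scan day that holds 12, 16 and 20 weeks, with fewer arrays, 3025 genes passed between 16 and 12 weeks and 1479 between 20 and 16 weeks. Without replicates 5 and 6 at 12 weeks 2279 genes passed at 12 weeks (572 higher) and 5312 between 12 and 8 weeks (2254 higher). At 10 days the genes higher in NOD were 100 with the Feature Extraction version as a block, 52 with the scanner and 45 with the covariates.

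Fits to the compared groups only, with fewer arrays to estimate the spread, gave 4 genes at 8 weeks, 1 at every age, 4983 between 8 and 4 weeks, 1602 between 12 and 8 weeks, 2785 between 16 and 12 weeks, 1258 between 20 and 16 weeks and 7817 between 20 weeks and 10 days. Leaving out single arrays gave from 87 (without replicate 1) to 325 (without replicate 2) genes at 8 weeks, where 101 passed without replicate 3. It gave from 2255 (without replicate 4 at 8 weeks) to 4236 (without replicate 6 at 12 weeks) between 12 and 8 weeks, and from 1402 (without replicate 3 at 20 weeks) to 2898 (without replicate 1 at 20 weeks) between 20 and 16 weeks, where 1469 passed without replicate 5 at 20 weeks.

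Size limits act by construction. Without one, 2318, 12024, 820, 9568, 9785 and 7486 genes passed against the control from 10 days to 20 weeks and 19 at every age. With a difference of at least 1 on the log2 scale, 4028 genes passed between 4 weeks and 10 days, 3822 between 8 and 4 weeks, 1169 between 12 and 8 weeks, 1137 between 16 and 12 weeks, 1022 between 20 and 16 weeks, 5343 between 20 and 4 weeks and 1659 between 20 weeks and 10 days. Camera with an estimated correlation left 8 list shifts and 0 mean-ratio lists, and fry, whose mixed test asks for change in either direction, gave 206 and 35.

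With the acinar and islet scores as covariates, which remove the pancreatic lists by construction, 164 genes passed at 8 weeks, 524 at 12 weeks, 1148 at 16 weeks, 2051 between 12 and 8 weeks and 9 between 20 and 16 weeks, and 8 mean-ratio lists passed. Because the islet scores at 16 and 20 weeks did not overlap, the covariates can also take up differences between these ages of any source. Reversed mean ratios were acinar 0.10, islet 0.063, epithelium 0.027 and type I interferon -0.10. Reversed shifts were acinar 0.10 (12 and 8 weeks) and -0.25 (20 and 16 weeks) and oxidative phosphorylation -0.078 (20 and 16 weeks). None of these passed. The islet list between 8 and 4 weeks kept a negative median (-0.19) while its test turned upward.

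The NOD channel alone gave 7094 genes between 12 and 8 weeks, 2772 between 16 and 12 weeks, 143 between 20 and 16 weeks, 4268 between 20 and 4 weeks and 10021 between 20 weeks and 10 days. It leaves out the control by construction. Of the named results, 43 genes and 24 lists changed direction there, and 69 genes and 27 lists lost the call. Between 4 weeks and 10 days the turned genes were Sbno2 (0.14), Per1 (0.36), H2-D1 (0.24), Afp (-1.01), Cstdc6 (-4.05), Ahsg (-2.94), Igfbp1 (-1.61), Hpx (-0.00075), Apoa2 (-1.77), Satb1 (0.27), Fcmr (1.04), S100a9 (-0.026), Ms4a3 (-0.035), S100a8 (-0.27), Cd74 (1.12), Aire (0.10), Foxp3 (0.46), H2-Aa (0.54), H2-Ab1 (0.80) and H2-Eb1 (0.67). Between 8 and 4 weeks they were Sostdc1 (0.029), Klf1 (-1.70), Hba-a1 (-1.15), Gcg (1.88), G6pc2 (1.34), Espl1 (-0.61), Epb42 (-1.07), Calr (-0.17), Pdia4 (-0.51) and Cd74 (-0.16), and between 12 and 8 weeks Klf1 (0.18) and Ptpn22 (-0.25). Mt2 stood at 0.73 between 20 and 4 weeks. Between 20 weeks and 10 days they were Sorl1 (0.11), Afp (-1.21), Fgg (-1.47), Mbl2 (-0.010), Apoa2 (-1.01), Fgb (-1.76), Il7r (0.049), Foxp3 (0.71), Ear1 (-1.22) and H2-D1 (1.12).

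The lists that turned in the NOD channel between 4 weeks and 10 days were liver (-0.27), T cells (0.23), B cells (0.40), circadian clock (0.36), immediate early (0.21) and MHC (0.35). Between 8 and 4 weeks they were islet (0.79), epithelium (-0.037), cell cycle (-0.34), stroma (-0.45), blood endothelium (-0.59), erythroid (-1.02) and oxidative phosphorylation (-0.031), between 12 and 8 weeks B cells (0.53), cell cycle (0.17) and ribosomal proteins (0.059), between 16 and 12 weeks stroma (-0.14) and between 20 and 4 weeks oxidative phosphorylation (0.12). Between 20 weeks and 10 days they were liver (-0.40), T cells (0.19), B cells (0.77), cell cycle (-0.062), regulatory T cells (0.36) and MHC (0.58).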

Other observations

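The test of the Deaf1 probe and the count of genes by position on chromosome 17 were chosen only after the results were seen, while the lists and their tests were fixed earlier.

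The chromosome 17 genes that passed at every age without a size limit lay, in the order of the gene table, as Gfer, Gnptg, Stk38, Dnah8, Zfp871, Wdr46, H2-DMb1, D17H6S56E-5, H2-T23, H2-T-ps, H2-T10 and H2-T3. Between the outermost of them lay 337 of the 918 tested genes of that chromosome, with 179 before and 402 after. A stretch as short had a permutation p of 8e-05, and the excess of chromosome 17 among the 14 of the 19 genes with a known chromosome (12 of 918 tested genes against 2 of 18404) a p of 1.03e-14 (Fisher's exact test). Some lists passed in no comparison of ages nor for the mean ratio. These were skeletal muscle (smallest adjusted p = 0.164), plasma cells (0.282), germinal centre and follicular helper T cells (0.0556), T helper and inflammatory cytokines (0.358) and lymphocyte precursors (0.513).

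Reference signals of arrays at different ages correlated at a median r of 0.965 across probes when scanned on the same day and 0.897 when scanned on different days, and 1 day held 3 ages while the other days held 1 each.

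A hypothesis is that the bright Deaf1 probe reports an acinar transcript. Its deviations from the age means followed the acinar score over 34 arrays (r = 0.927, rho = 0.947, permutation p = 1e-05 for both, the smallest 100000 permutations can give, adjusted p = 3e-05 over 3 probes), with r = 0.904 without the 2 arrays farthest from the median and r = 0.923 over 17 arrays of 1 scan day. The other 2 Deaf1 probes had r = 0.0931 (p = 0.60) and r = 0.109 (p = 0.53) over all ages, and r = 0.490 (16 arrays) and -0.0197 (17 arrays) within that scan day. Of 40837 probes, 48 others followed the acinar score as closely, 34 of them probes of the genes that make up the score and 14 of other genes, and probe sequences were not used here. The values go with an acinar source of the signal of this probe, and a change of Deaf1 itself with age may still add to it and was not tested.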
